A study of Homo sapiens with 24 samples.

How the data were processed

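Gene expression was measured in PFSK1 cells, an established human primitive neuroectodermal tumour line, on 24 Agilent 1-colour arrays. Per the labels' protocols, cells received non-target siRNA (siNTC) or siRNA against SLFN12 (siSLFN12) for 48 h and then DMSO or OPB-171775 for 8 h or 24 h, which makes 8 groups of 3 arrays. The labels describe 3 independent experiments at each time point. Per the labels' protocols, total RNA was prepared with RNeasy kits and labelled with Cy3 by the Quick Amp kit.

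The deposited scanner files hold spot intensity, and per the file headers this is the processed signal of Agilent Feature Extraction 11.0.1.1 under its 1-colour protocol, which subtracts background and spatial trends within each array and does no scaling between arrays. Per the file headers the probes are annotated on human build hg19. The reference table supplied for names is of another build, so no gene coordinates are given. The authors also deposited a table of log2 values for 27097 probes. How that table was made is not stated. From its values, columns differed by at most 0.002585 at the same rank, with a median of 8.54, as after quantile normalization, and each column's correlation with the scanner log2 values of its array was at least 0.9997, so it was not centred by gene. That table served only as an alternative.

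The array holds 58201 different probes besides controls. Spots called non-uniform or population outliers by the scanner software were left out, 81 to 117 per array, and the spots of a probe were averaged. Processed signals were put on the log2 scale, and each array's 75th percentile over the probes other than controls was subtracted. Levels are therefore log2 values relative to that percentile, which was 382 to 522 intensity units before scaling. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which held for 31621 probes. Of these, 21721 carried a gene symbol and 9900 carried none. Each gene was represented by its probe with the highest mean over the 24 arrays, which gave 16247 genes, 7 of them with a missing value. Of 58201 probes 31100 matched 1 symbol, 27101 matched none and 0 matched several. Among 4324 genes with several kept probes, probes passed the test in opposite directions for 107 genes after OPB-171775 in siNTC cells at 24 h and for at most 60 in any other comparison.

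A linear model with 1 mean per group was fitted to all 24 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom. A total of 9 comparisons were made: OPB-171775 against DMSO in each siRNA arm at each time, the difference of that response between arms at each time, siSLFN12 against siNTC in DMSO at each time, and the difference of the siNTC response between 24 h and 8 h. Genes passed at an adjusted p (Benjamini-Hochberg over all genes of a comparison) under 0.05. All adjusted p-values given come from limma. Standard errors (SE) are those of the fitted log2 fold changes, and standard deviations (SD) are between the 3 arrays of a group. Every group has n = 3.

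Before the data were examined, 28 gene lists with 524 members were written, of which 470 were measured. Of these lists 26 with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Glia markers had 4 measured members and were not tested, and the 9 drug target genes were reported as values only. Camera was repeated with a correlation estimated from the arrays. The self-contained test fry was also run, and it does not compare a list with other genes. Members that passed were counted over all genes and adjusted over the list alone.

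Also fixed before the data were examined was the rule for naming genes. For each comparison it takes the 10 highest and the 10 lowest log2 fold changes among genes that passed and moved the same way in all 3 same-numbered differences. For each list it adds up to 4 members that passed, by size of change, or with none the 2 with the largest change, and all measured drug target genes. Not all of these are printed, and results of some genes are not reported here. Every gene named as changed in the report moved the same way on all 3 slides. A gene not well above background on any array of 1 group is called dim there, and its change is given as at least the fold between the other group's mean and the background limit of the dim arrays.

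Per the file headers, the replicate number is the slide: each of 3 slides carries 1 array of every group and was scanned at once. Replicate numbers therefore pair the samples. As a check, deviations from the group means were correlated between arrays, and those with the same number had correlations of 0.0913 to 0.773 while the highest for different numbers was 0.0758. The lowest same-number value belonged to replicate 2 of the siSLFN12 groups at 24 h. The block for replicate number was an alternative fit.

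Calls were tested on simulated data with 16240 genes in which 67, 67 and 66 genes were changed by log2 values of 0.5, 1 and 2. At a log2 change of 1, the share recovered was 88.1% for OPB-171775 in siNTC cells at 8 h, 88.1% at 24 h, 80.6% in siSLFN12 cells at 8 h, 80.6% at 24 h, 82.1% for siSLFN12 at 8 h and 82.1% at 24 h. For the difference between arms it was 76.1% at 8 h and 65.7% at 24 h, and for the difference between times 67.2%. At a log2 change of 0.5 the shares ran from 29.9% to 58.2%, and at 2 from 87.9% to 98.5%. Far more genes passed in real siNTC cells at 24 h (52.2%), and the adjusted p depends on the share of changed genes. The recovered shares therefore do not describe the sensitivity of comparisons with many changed genes. False calls numbered 0 to 3 per comparison without the block and 7 to 18 with it. All planted lists were recovered and 0 of 20 unchanged lists were called in each comparison, in fits with the replicate block. Simulated genes varied independently beyond the slide, so this check cannot show how often lists of correlated genes are falsely called. In the real arrays the estimated correlation of a list reached 0.590, for ribosomal proteins.

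Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the E1A spike-in probes, no filter on dim probes, a filter on all 24 arrays, the mean of a gene's probes, the authors' log2 table, the replicate block over all arrays or within each time, a fit on only the groups compared, eBayes with trend and robust options, array weights, a 2-fold minimum and each array or slide left out. The files hold no mean spot signal, so normexp used the median spot signal. Added after the data were seen were the unnamed probes as features, the alternatives for correlations, and lists of small nucleolar RNA host genes and of motile cilium genes. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.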

Results

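The data were 24 arrays of PFSK1 cells in 8 groups of 3, made of every combination of siNTC or siSLFN12, DMSO or OPB-171775, and 8 h or 24 h of exposure. OPB-171775 is a compound described as acting through the phosphodiesterase PDE3A and SLFN12, a ribonuclease of the Schlafen family. The labels describe 3 independent experiments per time point. Between 52.6% and 59.3% of spots per array were well above background, and 0 spots were saturated. With 3 arrays per group, the number of arrays limits the precision. Pearson's r across genes between replicate arrays of a group was 0.989 to 0.996. The first principal component held 32.5% of the variance and followed the groups (R2 0.999), and the second held 24.7% and followed the slide (R2 0.956). Every group lay at the same position on all 3 slides, so position and group cannot be told apart.

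SLFN12 transcript fell after siSLFN12 in DMSO by a log2 fold change of -3.05 (SE 0.10, 8.30-fold, adjusted p = 1.73e-12) at 8 h and of -2.75 (SE 0.10, 6.73-fold, adjusted p = 1.07e-11) at 24 h. With normexp background correction the log2 fold changes were -2.18 and -2.04. On the log2 scale relative to the array's 75th percentile, the SLFN12 level was 0.48 ± 0.06 (SD, n = 3) with siNTC and -2.58 ± 0.07 with siSLFN12 in DMSO at 8 h. The level at 24 h was 0.49 ± 0.06 with siNTC and -2.26 ± 0.14 with siSLFN12. Every siSLFN12 array lay below every siNTC array. With OPB-171775 at 24 h in siNTC cells the SLFN12 level was 0.11 ± 0.11, and SLFN12 fell by a log2 fold change of -0.37 (SE 0.10, adjusted p = 0.00496). Spike-in scaling moved the median of all genes upwards by 0.26 in this comparison, so the size of that fall depends on the scaling. PDE3A rose in the same comparison by 0.61 (SE 0.15, adjusted p = 0.00193). PDE3B (-0.16, adjusted p = 0.133) and SLFN5 (-0.01, adjusted p = 0.956) did not pass. Against the siSLFN12 response at 24 h, SLFN12 (-0.38, adjusted p = 0.0414) differed. PDE3A (0.54) did not pass over all genes (adjusted p = 0.0506), but did so adjusted over the list alone and with the replicate block (adjusted p = 0.0309). At 8 h after OPB-171775 in siNTC cells, PDE3A at 0.29 (adjusted p = 0.392) and SLFN12 at -0.21 (adjusted p = 0.331) did not pass. After siSLFN12 alone PDE3A was at -0.18 (adjusted p = 0.575) at 8 h and -0.17 (adjusted p = 0.595) at 24 h. SLFN11, SLFN13 and SLFN14 were well above background on 0 arrays and SLFN12L on 1, so they were not tested.

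**Figure D1:**
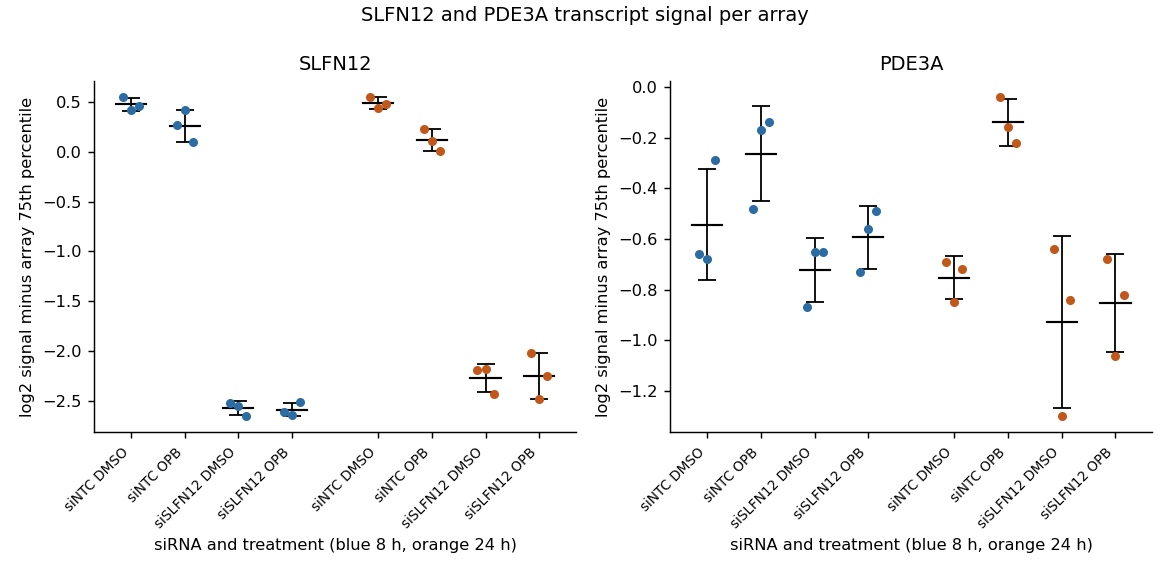
Levels of SLFN12 and PDE3A (log2 signal relative to the array's 75th percentile) by group, with 1 point per array and the mean ± SD of 3 arrays, in blue at 8 h and in orange at 24 h. SLFN12 means lie between 0.11 and 0.49 with siNTC and between -2.59 and -2.25 with siSLFN12, and PDE3A has its highest mean, -0.14, with siNTC and OPB-171775 at 24 h.

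OPB-171775 at 8 h in siNTC cells raised genes of the integrated stress response, immediate early genes and cAMP targets, and lowered heat shock genes. CHAC1, which encodes a glutathione-degrading enzyme induced by ATF4, rose by a log2 fold change of 2.34 (SE 0.11, 5.06-fold, adjusted p = 1.64e-10). DDIT3, the stress-induced transcription factor CHOP, rose by 1.87 (SE 0.07, 3.65-fold, adjusted p = 5.14e-12). TNFAIP3, a feedback inhibitor of NF-kB, rose by 2.01 (SE 0.17, 4.04-fold, adjusted p = 5.30e-07), and the orphan nuclear receptor gene NR4A2 by 2.09 (SE 0.24, 4.25-fold, adjusted p = 2.11e-05). HSPA1B, an inducible HSP70 gene, fell by 1.06 (SE 0.09, 2.09-fold, adjusted p = 4.61e-07). Further genes at the upper end were TCIM (2.18), EDN1 (1.56), ULBP1 (1.53), DDIT4 (1.45) and ATF3 (1.43), and CD69 was at least 1.58-fold higher. Lower were KRTAP25-1 (-1.22), CCL7 (-1.10), MGAT3 (-0.85), ZNF483 (-0.75) and TNFRSF10D (-0.67), and CCNJL was at least 1.75-fold lower.

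Among gene lists at 8 h, 17 of 23 measured ATF4 and integrated stress response targets rose and 0 fell (19 rose adjusted over the list alone), with a median log2 fold change of 0.77 (camera adjusted p = 2.62e-41, and 6.86e-07 with an estimated correlation). Of 22 immediate early genes 12 rose and 0 fell (18 adjusted over the list alone), among them ZFP36 (0.90), KLF6 (0.85) and KLF2 (0.83). Of 14 cAMP and CREB targets 8 rose and 0 fell (10 adjusted over the list alone), with NR4A3 at 0.81, SIK1 at 0.77 and CREM at 0.77. Of 16 heat shock genes 9 fell and 0 rose (12 adjusted over the list alone), with DNAJB1 at -0.58, HSPA8 at -0.53 and DNAJA1 at -0.41. Their median was -0.30 (adjusted p = 0.000336 with an estimated correlation), and -0.18 with spike-in scaling, where 2 fell. Those 4 lists passed both camera tests. The immediate early and cAMP lists share NR4A1, NR4A2, NR4A3, FOSB and DUSP1, so their results are not independent.

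Further lists at 8 h passed only with the preset correlation. NF-kB and cytokine genes had 4 of 20 higher and 1 lower (10 and 1 adjusted over the list alone), with CXCL2 at 1.12 and RELB at 0.72 (adjusted p = 0.136 with an estimated correlation). With the replicate block 12 of these were higher, and the list passed the same test (adjusted p = 0.00505). Histone genes had 3 of 16 higher (13 adjusted over the list alone, 9 with the replicate block), with H1-4 at 0.36 and H4C8 at 0.31 (adjusted p = 0.0806 with an estimated correlation). p53 targets had 3 of 20 higher and 1 lower (4 and 2 adjusted over the list alone), with BBC3 at 0.97, AEN at 0.60 and ZMAT3 at -0.50 (adjusted p = 0.0833 with an estimated correlation). BCL2 family and caspase genes had 3 of 22 higher, PMAIP1 at 1.16 and BCL2L2 at 0.28 among them (adjusted p = 0.213 with an estimated correlation). Among 19 tRNA synthetase genes 5 rose, for example CARS1 (0.43) and GARS1 (0.32), and the list's adjusted p = 0.112 with an estimated correlation. Small negative medians of DNA replication, mitosis, cholesterol synthesis, oxidative phosphorylation, proteasome and ribosomal protein genes, between -0.10 and -0.06, turned positive with spike-in scaling, and for ribosomal proteins also with quantile normalization. Their adjusted p-values with an estimated correlation were 0.414, 0.499, 0.369, 0.145, 0.204 and 0.488. At most 2 members of each passed, such as CCNE1 (-0.37), CCNA2 (-0.39), COX7B (-0.21) and PSMC6 (-0.31). NRF2 targets had OSGIN1 lower (-0.34, list adjusted p = 0.440 with an estimated correlation). The remaining lists passed neither camera test. ER chaperones and XBP1 or ATF6 targets had HERPUD1 (0.61) and XBP1 (0.50) higher of 17 measured. Hypoxia genes had VEGFA higher (0.66), ribosome biogenesis genes had WDR43 lower (-0.28), and neural progenitor markers had SOX2 lower (-0.44). Interferon-stimulated genes, autophagy genes and markers of neurons, glia, epithelium, mesenchyme and blood had 0 members past the threshold.

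In limma's test 845 of 16247 genes passed at 8 h, 557 higher and 288 lower, and 34 of these changed at least 2-fold. With the replicate block 2220 passed, 1111 higher and 1109 lower. Leaving out slide 2 gave 126, and spike-in scaling gave 556. Spike-in scaling moved the median of all genes by 0.12, and 98.2% of its calls were higher against 65.9%, so changes here are relative to the 75th percentile.

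OPB-171775 at 24 h in siNTC cells raised DDIT3, TRIB3 and TXNIP and lowered MAP2K6, CCL7, CCL2 and CCNE1, among others. DDIT3 rose by 2.81 (SE 0.07, 7.04-fold, adjusted p = 1.27e-15) and TRIB3, a pseudokinase gene induced by DDIT3, by 2.73 (SE 0.06, 6.63-fold, adjusted p = 6.06e-16). TXNIP, which encodes a thioredoxin-binding protein, rose 11.3-fold (SE 0.33 on the log2 scale, adjusted p = 5.39e-08). MAP2K6, a kinase gene upstream of p38, fell by 3.78 (SE 0.08, 13.8-fold, adjusted p = 5.12e-16). The chemokine genes CCL7 and CCL2 fell by 5.02 (SE 0.31, 32.4-fold, adjusted p = 1.96e-10) and by 2.69 (SE 0.13, 6.44-fold, adjusted p = 1.15e-11), and CCL7 remained well above background on 2 of the 3 OPB-171775 arrays. CCNE1, the cyclin E gene, fell by 1.49 (SE 0.05, 2.81-fold, adjusted p = 1.79e-13). Further genes at the upper end were SLC38A1 (3.10), NIBAN1 (2.98) and LARP6 (2.95), and TLR3, BEST1, CFAP206 and SCRG1 were at least 2.78-fold, 2.96-fold, 2.84-fold and 3.02-fold higher. At the lower end were MALL (-3.57), SYNPR (-3.05), SNORA30 (-2.97) and FBN3 (-2.85), and ADAMTS18, TMEFF2, ELOVL2-AS1 and CRB1 were at least 6.38-fold, 4.68-fold, 2.73-fold and 1.64-fold lower.

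**Figure D2:**
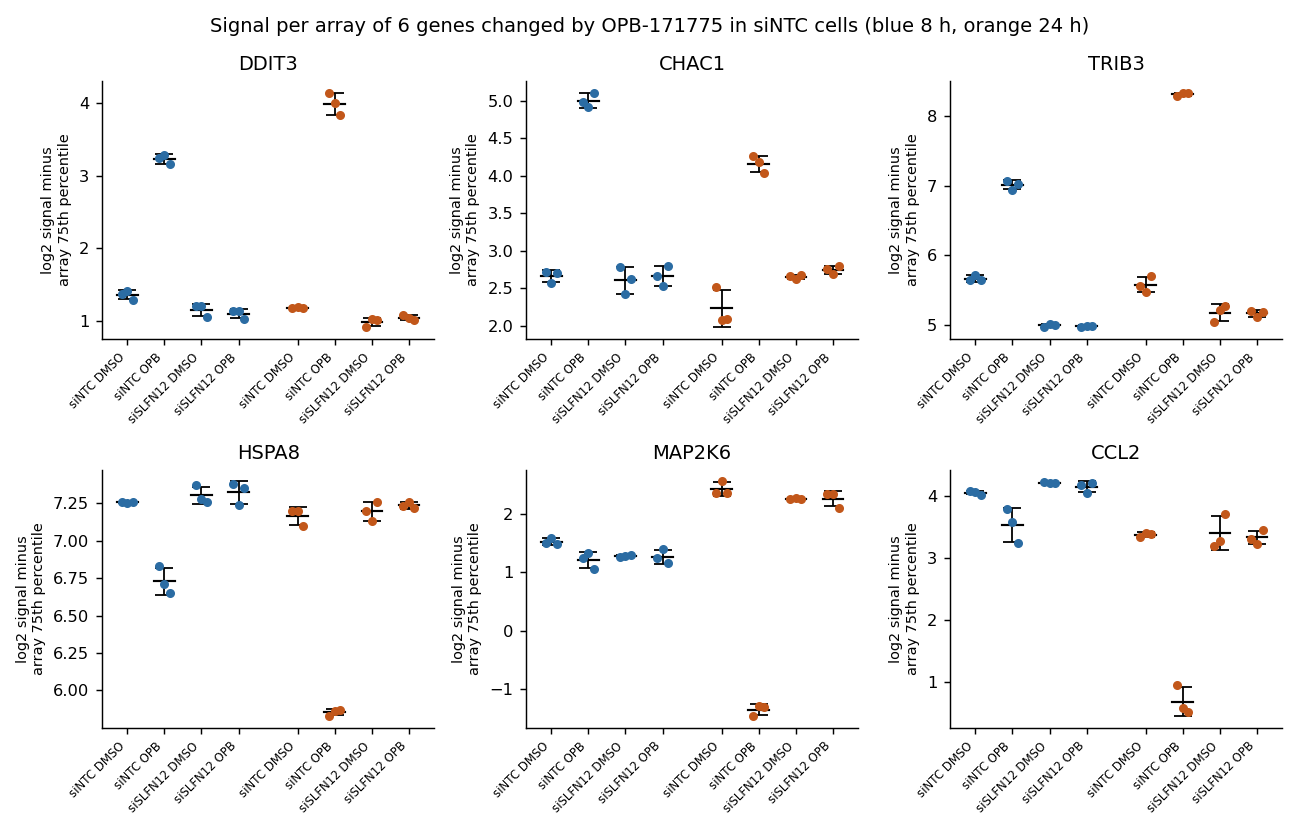
Levels of DDIT3, CHAC1, TRIB3, HSPA8, MAP2K6 and CCL2 (log2 signal relative to the array's 75th percentile) by group, with 1 point per array and the mean ± SD of 3 arrays, in blue at 8 h and in orange at 24 h. With siNTC at 24 h DDIT3 means 1.18 in DMSO and 3.99 in OPB-171775, and with siSLFN12 0.98 and 1.04.

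At 24 h, 20 of 23 ATF4 and integrated stress response targets rose and 1 fell (21 and 1 adjusted over the list alone), with NUPR1 at 2.50 and PPP1R15A at 2.15 (adjusted p = 0.00117 with an estimated correlation). Of 19 tRNA synthetase genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), led by WARS1 at 1.80 (SE 0.07, 3.48-fold), CARS1 at 1.62 and SARS1 at 1.52. That list's adjusted p = 0.0188 with an estimated correlation became 0.112 with the replicate block as well. Of 16 heat shock genes 15 fell (15 adjusted over the list alone), HSPA1B by 1.71 (SE 0.09, 3.28-fold), AHSA1 by 1.36 and HSPA8 by 1.31, with an adjusted p = 0.00874 with an estimated correlation that became 0.0760 with the replicate block as well. Only these 3 lists passed with an estimated correlation. Of all genes 52.2% passed at 24 h, so a count of members near that share is no sign of a response of the list.

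Of 23 mitosis genes 22 fell at 24 h and 0 rose (22 adjusted over the list alone), BUB1 by 1.75 and CDK1 by 1.52 (median -0.81, adjusted p = 0.0813 with an estimated correlation). Of 26 DNA replication genes 23 fell and 0 rose (23 adjusted over the list alone), CCNE1 as given and RFC4 by 1.34 (median -0.61, adjusted p = 0.0813 with an estimated correlation). Spike-in scaling gave 13 lower and 3 higher for DNA replication. Of 16 histone genes 15 fell and 1 rose, both over all genes and adjusted over the list alone, H1-5 by 1.93, H1-3 by 1.91 and H3C10 by 1.90 (median -1.26, adjusted p = 0.0913 with an estimated correlation).

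Of 20 cholesterol synthesis genes 14 fell and 2 rose, also adjusted over the list alone, INSIG1 by 0.92 in the lower direction and SC5D by 1.03 in the upper (adjusted p = 0.259 with an estimated correlation). Of 24 proteasome genes 15 were lower and 1 higher (16 and 1 adjusted over the list alone), PSMC6 at -1.28 and PSMD12 at -0.89, but the list's median of -0.20 was 0.06 with spike-in scaling, where 6 were lower and 5 higher (adjusted p = 0.359 with an estimated correlation). Of 23 oxidative phosphorylation genes 8 were lower and 1 higher, NDUFA1 at -0.69 and NDUFA2 at -0.53, and with spike-in scaling 2 were lower and 6 higher (list adjusted p = 0.0557). Of 26 ribosomal protein genes 4 were lower, RPL7A at -0.50 and RPS15 at -0.31, with 4 lower and 4 higher under quantile normalization and 1 lower and 11 higher with spike-in scaling (list adjusted p = 0.362). Of 20 ribosome biogenesis genes 10 rose and 4 fell, also adjusted over the list alone, RRP12 by 1.35 and PES1 by 0.80 in the upper direction (adjusted p = 0.443 with an estimated correlation). NRF2 targets had 6 of 15 lower and 2 higher, with AKR1B10 at -1.18 and HMOX1 at 0.67, and 2 lower and 3 higher with spike-in scaling. Hypoxia and glycolysis genes had 5 of 17 higher and 5 lower, with ANKRD37 at -1.15 and NDRG1 at 0.84.

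Inflammatory and death-related lists went both ways at 24 h, as did all genes, of which 4132 of 16247 were higher and 4352 lower. None of the lists in this paragraph passed with an estimated correlation. BCL2 family and caspase genes had 12 of 22 higher and 2 lower, also adjusted over the list alone, with PMAIP1 at 1.73, the BH3-only gene HRK at 1.70 and BID at -0.90 (adjusted p = 0.25 with an estimated correlation). Immediate early genes had 12 of 22 higher and 3 lower (13 and 3 adjusted over the list alone), with KLF2 at 1.71 and JUN at 1.43 (adjusted p = 0.0813 with an estimated correlation). NF-kB and cytokine genes had 6 of 20 higher and 2 lower, with CCL20 at 1.69 and RELB at 1.47 (adjusted p = 0.108). With the replicate block 11 were higher and 3 lower, and the preset test passed (adjusted p = 0.0364). Interferon-stimulated genes had 7 of 18 higher and 5 lower, with IFIH1 at 1.87 and IFIT1 at -2.04. cAMP and CREB targets had 6 of 14 higher and 3 lower, with CREM at 1.72 and FOSB at -0.88. p53 targets had 6 of 20 higher and 6 lower, with AEN 2.84-fold higher, POLH at -1.03 and SESN1 at -0.72. Autophagy genes had 7 of 18 higher and 7 lower, with GABARAPL1 at 2.05 and ULK1 at -0.70. ER chaperones and XBP1 or ATF6 targets had 6 of 17 higher and 2 lower, with XBP1 at 1.31 and HSPA5 at 0.54, and their median of -0.06 differed in sign from their mean of 0.11. Among cell type markers, SOX2 fell by 1.49 (SE 0.09) and HES1 by 0.62 of 8 neural progenitor markers, of which 3 fell. Neuron markers had 4 of 10 higher, SYT1 at 2.74 for example, and 3 lower, such as NEFM at -1.37. Epithelium markers had EPCAM at -0.95 and KRT18 at 0.56, mesenchyme markers LUM at -1.25 and TAGLN at 0.55, and blood markers had 1 of 6 lower. The glia marker SLC1A3 was at 0.30, but its mean over probes was -0.35.

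**Figure D3:**
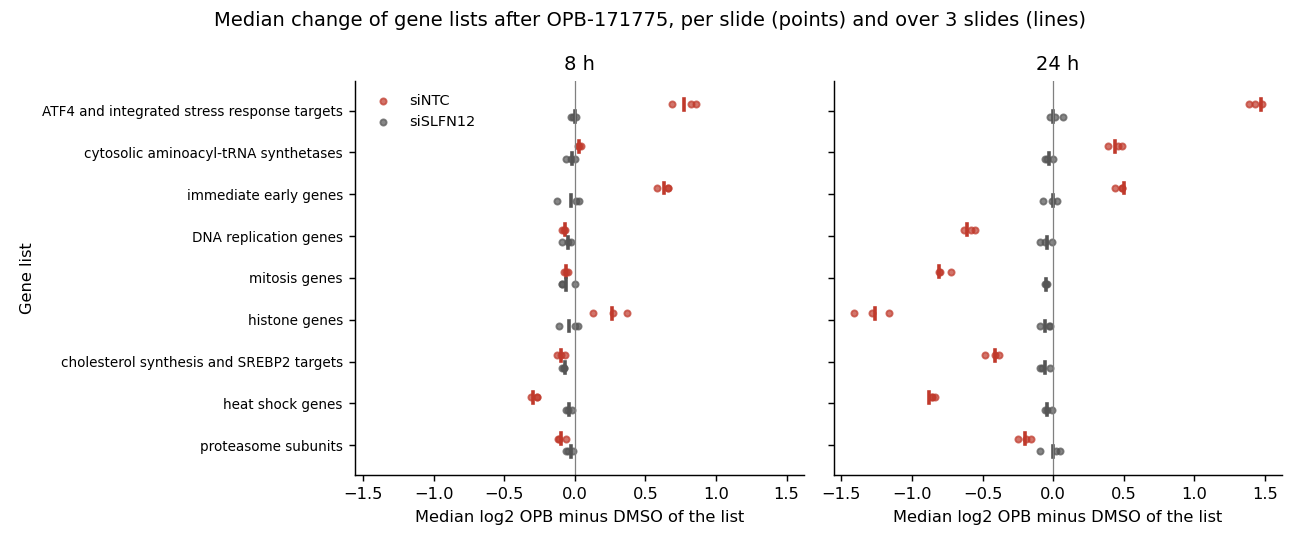
Median log2 fold change of OPB-171775 against DMSO for 9 gene lists on each of the 3 slides, siNTC in red and siSLFN12 in grey, at 8 h and 24 h, with 1 point per slide and a line over the 3. In siNTC cells at 24 h integrated stress response medians are 1.39 to 1.48 and heat shock medians -0.86 to -0.84.

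In limma's test 8484 of 16247 genes passed at 24 h (52.2%), 4132 higher and 4352 lower, and 1399 of these changed at least 2-fold, 663 higher and 736 lower. Spike-in scaling moved the median of all genes by 0.26, and 76.9% of its calls were higher against 48.7%.

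After SLFN12 knockdown, OPB-171775 gave 0 genes past limma's threshold at 8 h and 0 at 24 h, with 332 and 291 genes at an unadjusted p under 0.05. The replicate block gave 0 at both times, and the block within each time gave 0 at 8 h and 1 at 24 h. This comparison addressed whether the drug acts when SLFN12 transcript is lowered. The transcript was not absent, as it stayed well above background on all 3 arrays of each siSLFN12 group. Group means of DDIT3 were 1.15 ± 0.09 (SD, n = 3) in DMSO and 1.09 ± 0.07 with OPB-171775 at 8 h, and 0.98 ± 0.06 and 1.04 ± 0.04 at 24 h. HSPA8 had means of 7.31 ± 0.06 and 7.32 ± 0.08 at 8 h, and MAP2K6 of 2.27 ± 0.00 and 2.26 ± 0.13 at 24 h. Of all listed genes 0 passed. The median half-width of a gene's 95% confidence interval was 0.222, and 92.5% of genes at 8 h and 92.9% at 24 h had intervals inside 2-fold either way. In simulated data 43.3% of log2 changes of 0.5 were recovered at 8 h and 53.7% at 24 h. Camera with the preset correlation passed cholesterol synthesis genes at 8 h, and mitosis, ribosomal protein and cholesterol synthesis genes at 24 h. None passed with an estimated correlation (adjusted p = 0.884 at 8 h and 0.867 for each list at 24 h). cAMP and CREB targets at 24 h passed the preset test with the replicate block only (adjusted p = 0.0491 against 0.0687).

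**Figure D4:**
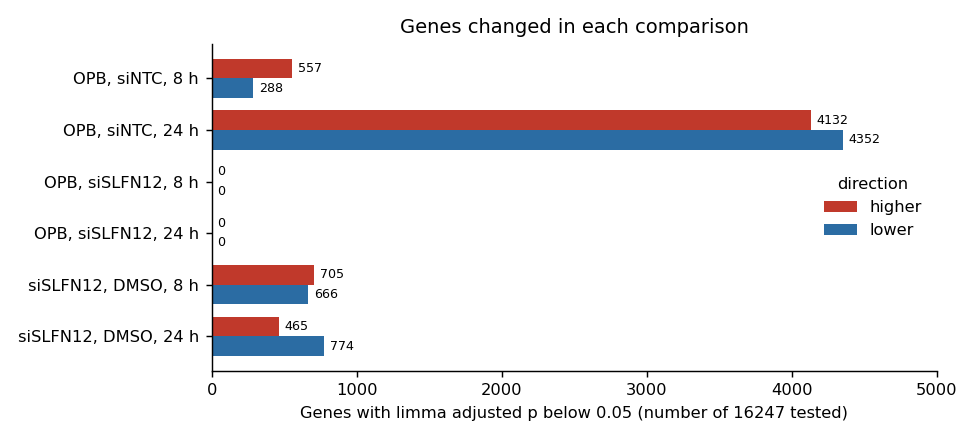
Number of genes higher (red) and lower (blue) at an adjusted p under 0.05 in limma, of 16247 tested, in 6 comparisons, drawn as neighbouring bars from 0. OPB-171775 gave 557 higher and 288 lower at 8 h and 4132 and 4352 at 24 h with siNTC, and 0 with siSLFN12.

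The response to OPB-171775 at 8 h differed between siNTC and siSLFN12 cells for genes of the integrated stress response and heat shock lists, among others. In the test of that difference, CHAC1 responded more in siNTC cells by 2.29 (SE 0.15, adjusted p = 8.23e-08), DDIT3 by 1.93 (SE 0.09, adjusted p = 1.23e-09) and TNFAIP3 by 1.89 (SE 0.24, adjusted p = 0.000166). HSPA1B was at -0.99 (SE 0.12, adjusted p = 0.000155), HSPA8 at -0.55 (SE 0.08) and DNAJB1 at -0.54 (SE 0.12). TCIM (2.09), NR4A2 (1.68), ULBP1 (1.53) and ATF3 (1.42) also differed upwards, and TOR4A (-0.72) and the receptor gene NOTCH3 (-0.62) downwards. Of 23 integrated stress response targets 14 differed, all upwards (17 adjusted over the list alone, adjusted p = 9.11e-07 with an estimated correlation). Of 22 immediate early genes 8 differed upwards (13 adjusted over the list alone, 14 with the replicate block) and of 14 cAMP and CREB targets 6 (8 adjusted over the list alone). Heat shock genes had 5 of 16 lower (6 adjusted over the list alone, 9 with the replicate block). These 4 lists passed with an estimated correlation, and NF-kB genes did so only with the replicate block (adjusted p = 0.00814 against 0.201). Members shared by the immediate early and cAMP lists count in both. Calls of histone and p53 lists (adjusted p = 0.0987 each), tRNA synthetases (0.111), BCL2 and caspase genes (0.122), NRF2, oxidative phosphorylation and proteasome genes (0.449 each) and ribosomal proteins (0.708) were lost with an estimated correlation. In all 292 genes differed, 268 upwards and 24 downwards. The count was 832 with the replicate block, 75 with spike-in scaling (74 upwards and 1 downwards) and 8 without slide 2.

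At 24 h the same test gave MAP2K6 at -3.78 (SE 0.11, adjusted p = 2.34e-13), CCL7 at -4.86 (SE 0.43, adjusted p = 8.17e-08) and TXNIP at 3.67 (SE 0.47, adjusted p = 5.21e-06). FBLIM1 (3.27), NIBAN1 (3.04) and LARP6 (2.95) responded more in siNTC cells, and the differences of MALL (-3.48), SYNPR (-3.07), ABTB1 (-2.78) and RCVRN (-2.74) were negative. Of 23 integrated stress response targets 20 differed upwards and 1 downwards, also adjusted over the list alone (adjusted p = 0.000765 with an estimated correlation). Of 19 tRNA synthetase genes 14 differed upwards and 1 downwards, also adjusted over the list alone (adjusted p = 0.0129 with an estimated correlation, 0.104 with the replicate block as well). Heat shock genes had 13 of 16 lower, also adjusted over the list alone (adjusted p = 0.00693 with an estimated correlation, 0.0660 with the replicate block as well). Mitosis genes had 18 of 23 lower, DNA replication genes 22 of 26, and histone genes 15 of 16 with 1 higher, and immediate early genes had 10 of 22 higher with 1 lower (adjusted p = 0.0830 for each list with an estimated correlation). Calls of BCL2 and caspase genes (0.25), cholesterol synthesis and proteasome genes (0.342 each), ribosome biogenesis genes (0.375) and oxidative phosphorylation genes (0.478) were also lost with an estimated correlation. The proteasome median of -0.20 was 0.01 with spike-in scaling, and the oxidative phosphorylation median of -0.10 was 0.11. The preset call of oxidative phosphorylation genes was lost with the replicate block (adjusted p = 0.0812). In all 6418 genes differed, 3303 upwards and 3115 downwards, and 1288 by at least 2-fold. Without slide 2 the count was 3501. Spike-in scaling moved the median of all genes by 0.21 here, with 76.9% of calls higher against 51.5%.

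Within siNTC cells the response at 24 h was tested against that at 8 h, to show which genes changed late. MAP2K6 was lower by 3.47 (SE 0.11, adjusted p = 1.07e-12) at 24 h relative to its 8 h response, and CCL7 by 3.92 (SE 0.43, adjusted p = 1.75e-06). NIBAN1 was higher by 2.60 (SE 0.55, adjusted p = 0.00123), ELOVL4 by 2.53 (SE 0.35) and LST1 by 2.58. Histone genes had 15 of 16 lower and 1 higher, also adjusted over the list alone (median -1.53), with H2AC11, a replication-dependent histone gene, at -3.12. Integrated stress response targets had 15 of 23 higher and 1 lower, also adjusted over the list alone. tRNA synthetase genes had 14 of 19 higher and 1 lower (15 and 1 adjusted over the list alone), heat shock genes 12 of 16 lower (13 adjusted over the list alone), and mitosis genes 20 of 23 lower (21 adjusted over the list alone). These 5 lists passed with an estimated correlation (adjusted p = 0.0274, 0.0232, 0.0214, 0.0214 and 0.0339 in that order). With the replicate block as well, none did (adjusted p = 0.125, 0.102, 0.101, 0.101 and 0.101). DNA replication genes had 19 of 26 lower (22 adjusted over the list alone, adjusted p = 0.0665 with an estimated correlation). Immediate early genes had 4 of 22 higher and 6 lower. Calls of ribosome biogenesis (0.394), cholesterol synthesis (0.437) and proteasome genes (0.621) were lost with an estimated correlation, and that of proteasome genes also with the replicate block alone (adjusted p = 0.0577). In all 5340 genes differed, 2784 upwards and 2556 downwards, and 2347 without slide 2. Spike-in scaling moved the median of all genes by 0.14, with 72.0% of calls higher against 52.1%.

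The siRNA against SLFN12 alone, in DMSO, lowered NOD1 and smooth muscle actin genes and raised TAC1, LRRC17 and CD96. Effects of SLFN12 loss and of the siRNA itself cannot be told apart for these genes. NOD1, an intracellular receptor for bacterial cell wall fragments, fell by 1.76 (SE 0.10, adjusted p = 3.47e-09) at 8 h and by 1.56 at 24 h. ACTA2 fell by 1.42 and 1.36, ACTG2 by 1.29 and 1.35, and CIB2 by 1.69 and 1.74 at 8 h and 24 h. MAPK8 fell by 1.19 (SE 0.13) and STX6 by 1.19 (SE 0.07) at 8 h. TAC1, the substance P gene, rose by 1.81 (SE 0.29, adjusted p = 0.000515) at 8 h and by 1.61 at 24 h. LRRC17 rose by 1.84 and 2.37, CD96 by 1.64 and 1.68, and UTS2 by 1.61 and 1.71. SLCO2B1 rose by 1.84 at 24 h, and CACNB4 and CPEB3 were at least 2.11-fold and 2.05-fold higher.

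Of 26 DNA replication genes 8 fell after the knockdown at 8 h and 9 at 24 h (12 and 12 adjusted over the list alone, 16 and 14 with the replicate block), CDC45 by 0.58 and FEN1 by 0.56 at 8 h (adjusted p = 0.441 at 8 h and 0.238 at 24 h with an estimated correlation). Mitosis genes had 0 of 23 past the threshold at 8 h and 8 lower at 24 h (14 adjusted over the list alone, 16 with the replicate block), AURKB by 0.38 and NUSAP1 by 0.39 (adjusted p = 0.238 with an estimated correlation). Histone genes had 1 of 16 lower at 8 h and 3 at 24 h (1 and 5 adjusted over the list alone, 9 at each time with the replicate block), and their adjusted p = 0.740 and 0.356 with an estimated correlation. At 8 h the positive medians of oxidative phosphorylation (0.12), proteasome (0.10) and ribosomal protein genes (0.06) turned negative with spike-in scaling (adjusted p = 0.740, 0.785 and 0.785 with an estimated correlation), and the ribosomal protein call was lost with the replicate block (adjusted p = 0.0556). ER chaperones at 8 h passed the preset test only with that block (adjusted p = 0.0209 against 0.0534). At 24 h tRNA synthetases and interferon-stimulated genes passed only with the preset correlation (adjusted p = 0.356 each with an estimated correlation), the former not with the replicate block (adjusted p = 0.0687). Of 23 integrated stress response targets 0 rose and 1 fell at 8 h, TRIB3 by 0.67, and 3 rose and 1 fell at 24 h, with SLC7A11 at 0.58, CHAC1 at 0.42 and TRIB3 at -0.40. Of 22 BCL2 family and caspase genes 3 rose and 2 fell at 8 h, with BIK at 1.14, PMAIP1 at 0.99 and BBC3 at -0.37, and 1 rose and 3 fell at 24 h, with BAK1 at 0.26, BBC3 at -0.39 and BAD at -0.36. COX4I1 fell by 0.75 and 0.73, while 3 other oxidative phosphorylation genes rose at 8 h, NDUFS3 by 0.22 for example. TAGLN fell by 1.03 and 1.07, while LUM rose by 0.52 at 24 h.

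In limma's test siSLFN12 changed 1371 genes at 8 h, 705 higher and 666 lower, and 1239 at 24 h, 465 higher and 774 lower. At least 2-fold changes were found for 41 and 54 genes. With the replicate block 4005 and 3825 genes passed. Leaving out slide 2 gave 143 and 94, and spike-in scaling gave 811 and 614. Spike-in scaling moved the median of all genes by -0.13 at 8 h, and 13.7% of its calls were higher at 8 h against 51.4% and 18.4% at 24 h against 37.5%. Of the calls at both times 801 were shared, where independent lists would share 105, and all of them moved the same way, where independent lists would give 51.9. The labels give no other SLFN12 siRNA treatment, so effects of SLFN12 loss and of the siRNA itself were not separated.

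Responses were also compared across genes, which are not independent replicates, between comparisons that share no arrays. In siNTC cells the log2 fold changes at 8 h and 24 h had r = 0.455 (Spearman's rho 0.469), and within single slides r was 0.374, 0.309 and 0.363. At both times 748 genes passed, where independent lists would share 441, and 716 of these moved the same way, where independent lists would give 219. Between siNTC and siSLFN12 cells r was 0.015 (rho 0.043) at 8 h and 0.044 (rho 0.008) at 24 h, with single-slide values of 0.012, 0.035 and 0.050 at 8 h and 0.008, 0.006 and 0.091 at 24 h. Genes that rose in siNTC cells at 24 h had a median log2 fold change of 0.54 there and -0.02 in siSLFN12 cells, and those that fell had -0.55 and -0.02. Between the siSLFN12 responses at 8 h and 24 h r was 0.293 (rho 0.406), and without slide 2 it was 0.165 (rho 0.152). The knockdown effects in DMSO at 8 h and 24 h had r = 0.706 (rho 0.684).

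**Figure D5:**
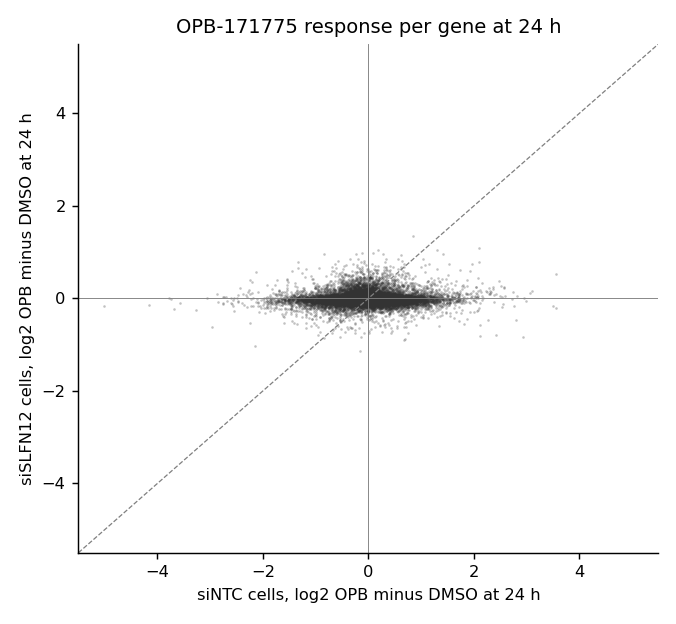
Log2 fold change of OPB-171775 against DMSO at 24 h for each gene, siNTC cells on the horizontal axis and siSLFN12 cells on the vertical axis, with 1 point per gene and a dashed line of equality. Pearson's r across genes is 0.044.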

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

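The tests of scaling and of exchanged labels were chosen only after the results were seen, as was the use of probes without a gene symbol. So was the comparison with splits that exchange equal numbers of OPB-171775 and DMSO arrays.

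Responses to OPB-171775 differed between siRNA arms by a test of the difference itself, for 292 genes at 8 h and 6418 at 24 h, and between times in siNTC cells for 5340 genes. Gene lists that differed with an estimated correlation numbered 4 between arms at 8 h, 3 between arms at 24 h and 5 between times. With the replicate block as well, camera added the NF-kB list at 8 h. At 24 h it then kept only the ATF4 and integrated stress response list (adjusted p = 0.0112), and between times none. Without slide 2 the genes numbered 8, 3501 and 2347, and the 8 h count was also below 292 by over 1.5 times without slide 1 (103), slide 3 (98), siSLFN12_DMSO_8h replicate 2 (194) or siNTC_OPB_8h replicate 3 (190).

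In 100 splits, the real one included, labels were exchanged among the OPB-171775 arrays and among the DMSO arrays. The labels exchanged were those of siRNA, or of time for the difference between times, and never those of the drug. Counts as high as the real one came from 10 splits at 8 h (highest other 4603), 9 at 24 h (highest other 7445) and 2 between times (highest other 5497). The 8 h count of 4603 is several times the real 292 and points to a structure of the samples. Splits that exchange unequal numbers of OPB-171775 and DMSO arrays turn the siRNA or time effect itself into a difference of responses, so they are no reference for chance. Among the 43 others that exchange equal numbers, the highest counts were 2 at 8 h, 1 at 24 h and 0 between times. These splits mix siRNAs or times within a group and move arrays across slides, which widens the spread and favours low counts. They are no reference for chance either. The rule set before, a share of splits under 0.05, was missed for both differences between arms and met between times. The splits therefore do not settle whether chance gave the 292, 6418 and 5340.

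For the simple comparisons the 6 arrays make 10 splits, too few for a share under 0.05. After OPB-171775 in siNTC cells 1 of 10 splits, the real one, gave as many genes as the real 845 at 8 h and 8484 at 24 h (highest other 0 at both). In siSLFN12 cells the real count was 0 at each time, so 10 of 10 splits reached it by construction (highest other 0 at 8 h and 2 at 24 h). After siSLFN12 alone 1 of 10 gave as many as 1371 at 8 h and 1239 at 24 h (highest other 1 at both). In each comparison 3 other splits also part all slide pairs, and they gave 0 genes. Where the groups differ, the other splits mix them, which widens the spread and favours low counts. Such splits are no reference for chance.

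OPB-171775 changed 8484 genes at 24 h with siNTC and 0 with siSLFN12. Scaling as the whole cause is argued against by spike-in scaling, under which 70.2% of the 6418 genes that differed between arms passed in the same direction. Exchanged labels in some siSLFN12 pairs would hide a response from the test but leave a positive or negative correlation with the siNTC response on single slides, and are argued against by the largest absolute r across genes there, 0.0912. Array position stays open, since each group had 1 position on all slides and so position and group cannot be told apart. A dependence of the drug response on SLFN12 may explain the pattern, as a hypothesis that these tests leave open beside position and effects of the siRNA other than on SLFN12.

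Probes without a gene symbol, outside the comparisons by gene, also changed after OPB-171775 in siNTC cells: 2454 of 9560 passed at 24 h, 1023 higher and 1431 lower, and 142 at 8 h. Their responses differed between arms for 53 at 8 h and 1629 at 24 h.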

How the results depend on the processing

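Alternatives for the correlations and the inclusion of unnamed probes were chosen only after the tests were seen. The SLFN12 level kept its direction and passed under every alternative, between -3.09 and -3.01 at 8 h and -2.82 and -2.67 at 24 h with arrays or slides left out, and at -2.18 and -2.04 with normexp. For counts outside 1.5 times the value first reported, the cause was not tested unless given.

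OPB-171775 in siNTC cells at 8 h gave 845 genes, 556 with spike-in scaling, 2220 with the replicate block, 2450 with that block within each time, 108 on only the groups compared (fewer arrays estimate the spread) and 1655 with array weights. With arrays or slides left out the count was 126 to 663, with 356, 126 and 334 without slides 1, 2 and 3, 557 without siNTC_DMSO_8h replicate 3 and 520 without siNTC_OPB_8h replicate 3. At 24 h the range was 5831 to 8018. In siSLFN12 cells no filter on dim probes gave 1 gene at 8 h, and at 24 h the block within time gave 1. Left-out arrays gave 0 at 8 h and 0 to 1 at 24 h, the 1 without siSLFN12_DMSO_24h replicate 3.

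The difference between arms at 8 h (292) was 75 with spike-in scaling, 832 with the replicate block, 1007 with the block within time, 119 on the groups compared and 533 with array weights, with 8 to 275 when arrays or slides were left out. At 24 h that range was 3501 to 6314. The difference between times (5340) was 8154 with the block within time, and 2347 to 5123 with arrays left out. In each case the lowest count came without slide 2. The model held no term for the slide, and slide 2 lay between slides 1 and 3 on the second principal component. Leaving it out kept the slides furthest apart, so these low counts do not show that the results rest on slide 2.

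After siSLFN12 alone, 1371 genes at 8 h and 1239 at 24 h became 811 and 614 with spike-in scaling, 4005 and 3825 with the replicate block, 4232 and 4057 with the block within time, and 137 and 76 on the groups compared, and array weights gave 2666 at 24 h. Left-out arrays gave 143 to 1349 at 8 h and 94 to 1248 at 24 h. Without slides 1 and 2 the counts were 476 and 143 at 8 h and 408 and 94 at 24 h. Without siSLFN12_DMSO_8h replicates 1 and 2 and siNTC_DMSO_8h replicate 3 they were 886, 811 and 820, and without siNTC_DMSO_24h replicates 2 and 3 and siSLFN12_DMSO_24h replicate 2 they were 787, 801 and 769.

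A 2-fold minimum by construction lowered the 7 counts above 0 to 34 and 1399 (siNTC at 8 h and 24 h), 24 and 1288 (between arms), 41 and 54 (siSLFN12) and 863 (between times). List tests passed 75 of 234 times, 19 with an estimated correlation, and 66 to 76 with a slide left out. Besides the values given with the results, the replicate block changed no other list call, and every gene that passed without it passed with it.

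The correlation of siNTC responses between times (0.455) was 0.537 with normexp, 0.301 with no filter, 0.518 with a filter on all arrays, 0.513 with the authors' table and 0.405 to 0.439 with a slide left out. That between arms at 8 h (0.015) was -0.022 with normexp and -0.012 to 0.037 with a slide left out, and at 24 h (0.044) -0.011 to 0.069. Of 577 passed values of named genes, 286 passed under every alternative they were measured in, other than the 2-fold minimum. The filter on all arrays and the authors' table held only 501 of the 577. RPL23 after OPB-171775 in siNTC cells at 24 h was reversed to 0.03 with spike-in scaling. SLC1A3 was reversed with the mean of its probes, to -0.35 at 24 h, -0.45 between arms and -0.29 between times. Between 52.6% and 59.3% of spots per array were well above background, which limits folds of dim genes to bounds.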

Other observations

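The lists and tests for small nucleolar RNA host genes and motile cilium genes, and the test of the share of a correlation kept without a trend on mean signal, were chosen only after the results were seen.

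Of 19 measured host genes of small nucleolar RNAs, long non-coding transcripts whose introns carry these RNAs, 10 rose and 0 fell after OPB-171775 in siNTC cells at 8 h (adjusted p = 0.00609 with an estimated correlation), and 15 rose and 2 fell at 24 h (adjusted p = 0.0760). SNHG1 rose by 1.08 at 8 h and 2.02 at 24 h, SNHG17 by 1.01 and 2.15, SNHG15 by 0.81 and 2.04, SNHG12 by 0.70 and 1.35, and ZFAS1 by 0.48 and 1.74. GAS5, a growth arrest-associated transcript, rose by 1.23 at 24 h. SNHG16 fell by 0.82 and SNHG4 by 0.62 at 24 h. In siSLFN12 cells 0 members passed at either time, also adjusted over the list alone. The median was 0.34 at 8 h and 0.99 at 24 h, and 0.46 and 1.25 with spike-in scaling.

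Genes of motile cilia, hair-like organelles of multiciliated cells, had 16 of 35 measured members higher and 2 lower after OPB-171775 in siNTC cells at 24 h, with a median of 0.38 and an adjusted p = 0.137 with an estimated correlation. The median was 0.19 with normexp (14 higher, 0 lower) and 0.64 with spike-in scaling (21 higher, 0 lower). CFAP206, CFAP251, CFAP263, RSPH10B and JHY were well above background on 0 DMSO and 3 OPB-171775 arrays, and were admitted by a filter that accepts 1 group. CFAP161, 1 of the 2 lower members (-1.10), was well above background on 0 arrays of either group and admitted through another. Of the 25 members well above background on all 3 DMSO arrays 9 were higher and 1 lower, with a median of 0.20. Of all genes 52.2% passed in this comparison, so the counts over 35 and over 25 members are no sign of a response of the list. DNAAF4, a dynein assembly factor gene, rose by 1.58 (SE 0.10) and CFAP53 by 1.33. MCIDAS, a regulator of multiciliated cell fate, rose by 1.92 (SE 0.58, adjusted p = 0.00917) and was well above background on 1 of the 3 DMSO arrays. At 8 h and in siSLFN12 cells 0 members passed, and 8 differed between arms at 24 h (14 higher and 1 lower with the replicate block, list adjusted p = 0.195 with an estimated correlation).

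For the host genes, many of whose transcripts are degraded by nonsense-mediated decay, lower decay when translation falls is a candidate explanation, as a hypothesis. It needs the list to rise against other genes at both times. With an estimated correlation the list passed at 8 h (adjusted p = 0.00609) but not at 24 h (adjusted p = 0.0760). The list was chosen from these same data, and a rise would not tell lower decay from another cause. The test therefore cannot decide, and the explanation stays open. Between arms the list's adjusted p was 0.00579 at 8 h and 0.0782 at 24 h. Decay itself was not measured.

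Below the threshold, responses of siSLFN12 cells correlated across genes between 8 h and 24 h, and that correlation was 0.305, 0.165 and 0.198 without slides 1, 2 and 3. An effect of OPB-171775 that needs no SLFN12 should also show in siNTC cells. The covariance of the siNTC response at 8 h with the siSLFN12 response at 24 h was 13.4% of that between the siSLFN12 responses (20.2%, 0.308% and 9.90% without slides 1, 2 and 3). These values met the bound set before for that pair of responses. The other such pair, which that bound did not cover, gave 4.78%, and from -65.3% to 117% with a slide left out. That pair varied too widely for the test to decide, so such an effect stays open. Removal of a trend on mean signal left r at 0.254 and kept 86.9% of it (89.9%, 80.1% and 87.6% without slides 1, 2 and 3), which argues against that trend as the whole cause, by a bound of 50% set after these values were seen. The bound set before, r over 0.2 with each slide left out, could not be met, as r was lower without slides 2 and 3 before any removal, so another bias that depends on signal stays open, as does array position, with 1 position per group.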
